A study of Mus musculus with 3 samples.

How the data were processed

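Gene expression was measured with 3 arrays on primary chondrocytes, the cells that build cartilage, cultured from the ribs of mouse embryos. BBF2H7, encoded by Creb3l2, is a transcription factor held in the membrane of the endoplasmic reticulum (ER), and its N-terminal part (p60) is the fragment that enters the nucleus. One 1-colour Affymetrix array held RNA of wild-type cells and 1 held RNA labelled BBF2H7 knockout. The third array was a 2-colour array of knockout cells infected for 30 h with an adenovirus expressing the N-terminal part (Cy3, channel 1) against knockout cells (Cy5, channel 2). Per the labels, no control virus is named for the Cy5 channel. Groups were taken from the sample titles and, for the 2-colour array, from the source name of channel 1. The source name of the knockout array says OASIS, the product of Creb3l1, where its title says BBF2H7, so both genes are reported.

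The 1-colour values are log2 expression per probe set, as deposited by the authors. Per the submitters' processing notes they were made by RMA (background correction, quantile normalization and summary of the probes of a set) in Affymetrix Expression Console 1.1, and per the labels' protocols the RNA was amplified in a two-cycle biotin labelling. Which arrays were normalized together is not given in the sources used here. The 2 arrays had near-identical distributions, with medians of 5.63 in both, and 1793 of 45101 probe sets (3.98%) had exactly the same value on both, so differences between them are relative to a fixed overall distribution. The 2-colour values are a log ratio per probe, as deposited by the authors, centred near 0. Their log base, direction, background correction and normalization are not given in the sources used here. They were read as log2, because the highest value of 11.5 would mean a 2848-fold ratio in base 2 and a ratio of 2.99e+11 in base 10. Of 23473 probes, 3903 had no value. The direction was taken as likely infected over knockout after the values were seen: the infected cells are channel 1, the study design text speaks of genes raised by the N-terminal part, Creb3l2 and Sec23a have positive values, and genes known to respond to virus lie at the positive end. The signs of these genes are therefore no separate results. Channel order does not settle the direction, since a ratio of channel 2 over channel 1 would turn every sign. Counts with the sign turned are the same numbers with higher and lower exchanged.

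Gene names came from the platform annotation, with older symbols updated through gene identifiers or synonyms that point to 1 gene (59 symbols of the 1-colour array and 3947 of the 2-colour array). Of the 1-colour probe sets, 34958 had 1 symbol, 932 several and 9211 none, and only those with 1 symbol were used. Of the 2-colour probes, 16631 had 1 symbol and 6842 none. The 1-symbol probes found in the reference gene table numbered 34956 and 16569. No coordinates are given, because no genome build is named for either array.

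With 1 array per group there are no replicates and no test of any difference between the conditions; every count, difference and list median describes these arrays, and a gene is called by size alone. The 64 Affymetrix control probe sets were not removed, and those that carry a symbol (of Actb, Gapdh, Pcx and Tfrc) stood among the probe sets of these genes. A gene's value on the 1-colour arrays is that of its probe set with the highest mean log2 over both arrays, among probe sets whose mean lies at or above the median of all probe sets (5.63 log2). This left 11714 genes. The difference is the array labelled knockout minus wild type, and genes at least 2-fold apart were counted. The only spread that could be estimated is technical: between probe sets of 1 gene, the log2 difference had an SD of 0.18 (5352 genes with 2 or more probe sets). On the 2-colour array a gene's value is the mean over its probes (14169 genes); between probes of 1 gene the SD was 0.64 (170 genes). The number of arrays limits the precision, and neither SD holds the variation between cultures or animals.

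Before the data were examined, 21 gene lists, the rule for named genes and the alternative settings, other than those named below as added, were fixed. The lists cover the secretory pathway (COPII, COPI, ER translocation, N-glycosylation, ER chaperones, ER stress signalling, the CREB3 and ATF6 family, collagen modification), cartilage (matrix, regulators, hypertrophy and ossification), other cells that a rib culture could hold (fibroblasts, muscle, blood and macrophages, endothelium and fat, nerve), proliferation, the interferon response, hypoxia and glycolysis, sterol synthesis and cytosolic ribosomal proteins. The median of each list was set against the medians of 10000 random lists of the same size, drawn for the 1-colour arrays from the same of 20 bins of mean expression and for the 2-colour array from all genes with a ratio. A list is said to lie within the range of random lists when its median is within their middle 95%. The percentile describes these arrays only and is not a p-value, since genes of a list vary together. Named genes are Creb3l2, Creb3l1 and Sec23a. They include the 12 largest differences each way on the 1-colour arrays, provided that the mean over all probe sets of the gene was at least 1.5-fold the same way. Up to 6 members of each list at least 2-fold apart and the 10 largest ratios each way on the 2-colour array were named too. So were up to 20 genes at least 2-fold lower on the array labelled knockout and at least 1.5-fold up on the 2-colour array. These 20 were taken by the largest sum of both sizes. Symbols that look like clone names were counted but not named. Other list members named below are those with large or small values in their list, chosen after their values were seen.

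The script for the 1-colour comparison was tested on simulated arrays with the spread between probe sets as noise and 200 genes of known change. Of 50 genes set to a log2 change of 1.5, 98% were counted as at least 2-fold higher. Of 50 set to -1.5, 100% were counted as lower, and of 11514 others 0%. The 0% follows from the small noise, which held no variation between cultures. The test thus checks the script and does not tell how many called genes are false. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The alternatives were the median over probe sets, no floor, a floor at the 75th percentile, no _x_at or _s_at probe sets, a lowess curve subtracted, thresholds of 1.5-fold and 3-fold, unmatched random lists and, for the 2-colour array, median centring, the median over probes, the sign turned and, added after the data were seen, random lists matched on 1-colour expression and, for the counts, 1-colour values below the floor raised to the floor. The floor stands in for a detection limit, which was not measured.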

Results

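The data comprised 1 array of wild-type rib chondrocytes, 1 array labelled BBF2H7 knockout, and 1 2-colour array of knockout cells that received the BBF2H7 N-terminal part against knockout cells. The 1-colour arrays gave 11714 genes above the floor and the 2-colour array 14169 genes. Over the 11714 genes the 1-colour arrays correlated with a Pearson r of 0.986 (across genes, which are not independent replicates). There were no replicates, so no p-value is given and each value below is a single measurement.

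The targeted gene was examined first, because it checks the label. Creb3l2, which encodes BBF2H7, was not lower on the array labelled knockout: its 2 probe sets read 9.24 and 7.74 log2 units in wild type and 9.52 and 7.78 on the array labelled knockout. These are differences of 0.28 and 0.04, against an SD of 0.18 between probe sets of a gene. Creb3l1, which encodes the related factor OASIS named in the source field of that array, was not lower either, at 11.86 in wild type and 12.60 on the array labelled knockout, a difference of 0.73. Which part of Creb3l2 was removed is not given in the sources used here, so a probe set outside that part would check nothing. On the 2-colour array Creb3l2 had a log2 ratio of 0.96 and Creb3l1 one of -1.23. Whether the Creb3l2 probe of that array lies in the N-terminal part was not checked, so its ratio need not measure the introduced part. The third array is therefore described as infected over knockout, its likely direction, and the first comparison as the array labelled knockout against wild type.

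The first comparison asked which genes depend on BBF2H7 in these rib cultures, which need not hold chondrocytes alone. On the array labelled knockout 81 genes (0.69%) were at least 2-fold lower than in wild type and 46 (0.39%) at least 2-fold higher. Where 1 of a gene's values lay below the floor of 5.63 log2 units, which was so for 20 of the lower and 9 of the higher genes, its fold is given as a bound against the floor. Gal, the neuropeptide galanin, was at 9.23 log2 units in wild type and below the floor on the array labelled knockout (at least 12.1-fold lower). Trib3, a pseudokinase induced by the transcription factor ATF4, was 12.5-fold lower, and Chac1, a glutathione-degrading enzyme also induced by ATF4, was 9.33-fold lower. Egln3 and Car9, an oxygen-sensing prolyl hydroxylase and a carbonic anhydrase that are both induced by hypoxia, were at least 4.68-fold and 5.61-fold lower, and Ndufa4l2, a mitochondrial protein also induced by hypoxia, was 7.11-fold lower. Frzb, a secreted Wnt antagonist of cartilage, was 6.41-fold lower, with log2 differences of -2.68 and -3.40 on its 2 probe sets above the floor. Bcat1 (branched-chain amino acid transaminase) and Rbp4 (retinol-binding protein) were 6.29-fold and 6.11-fold lower, and Cth (cystathionine gamma-lyase) and the cation channel gene Nalcn at least 2.94-fold and at least 3.83-fold lower. Xist, the RNA of the inactive X chromosome, was at least 4.64-fold lower, while the Y-linked genes Eif2s3y, Uty and Kdm5d lay above the floor on both arrays. Their highest probe sets were at 8.66, 7.61 and 7.33 in wild type and at 9.11, 7.40 and 7.33 on the array labelled knockout, so that Eif2s3y was 0.45 higher there.

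In the other direction, Rbm45, an RNA-binding protein, was at 5.75 log2 units in wild type and 9.12 on the array labelled knockout (10.3-fold higher). Cap1, an actin regulator, was 5.97-fold higher, with differences of 2.57 and 2.58 on its 2 probe sets. Rasgrp2, a guanine nucleotide exchange factor, was at least 3.26-fold higher on its brightest probe set, but the lowest of its 3 probe sets differed by a log2 value of 0.20. The neuropeptide gene Cartpt was at least 4.24-fold higher, the phospholipase gene Pla2g5 4.19-fold and the neuronal microtubule gene Stmn2 at least 3.60-fold. Car3, a carbonic anhydrase abundant in fat and muscle, was 3.52-fold higher at a high level (11.70 and 13.51 log2 units). The anion transporter gene Slc26a7, Mamdc2 and the extracellular matrix gene Fras1 were 3.51-fold, 3.26-fold and 3.02-fold higher, and Gsg1 and the transcription factor gene Tbx2 at least 3.14-fold and at least 2.44-fold higher. Among the genes at least 2-fold apart either way, 42 had 2 or more probe sets above the floor. In all 42 every such probe set lay on the same side of 0, and in 37 all were at least 1.5-fold the same way. The remaining genes rest on 1 such probe set, and probe sets of a gene share the same RNA.

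The design text of the study names the protein secretory pathway and ER biogenesis as lower in the knockout. Sec23a, a component of the COPII coat of vesicles that leave the ER, was at 11.94 log2 units in wild type and 11.44 on the array labelled knockout, a difference of -0.50 or 1.41-fold. The COPII and ER-to-Golgi list had a median difference of -0.07 (percentile 0.08 of the random lists), or -0.12 after a lowess curve was subtracted. None of its 39 measured genes was 2-fold apart, 24 lay below 0, and 2 were at least 1.5-fold lower: Sec16b (-0.98), which organises ER exit sites, and the coat gene Sec24d (-0.61). Sec23a, the cargo receptor Surf4 (-0.46), the coat gene Sec24a (-0.43) and Mia2 (-0.43) came next, and Sec23b, the paralog of Sec23a, was at 0.22. The COPI and Golgi list had a median of -0.16, below all 10000 random lists, with 29 of 36 genes below 0. Its largest differences were in the KDEL receptor Kdelr3 (-0.49), Arfgap1 (-0.35) and the coat subunit Arcn1 (-0.34), and 0 of the 36 reached 1.5-fold. The lists of ER translocation (median 0.04, 22 genes, percentile 35.5) and N-glycosylation (0.06, 27 genes, percentile 59.5) lay within the range of random lists. The signal sequence receptor subunit Ssr1 (-0.23) and the signal peptidase subunit Sec11c (0.33) bounded the first, and the glucosyltransferase Alg6 (-0.74, with its value on the array labelled knockout below the floor) was the lowest of the second.

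The medians of ER chaperones and ER stress signalling genes lay on opposite sides of 0 on the same arrays. The median of the list of chaperones and degradation factors was 0.23, above all 10000 random lists (0.13, percentile 97.54, with the median over probe sets), with 25 of 35 genes above 0. Creld2 (0.67), Manf (0.63), the disulphide isomerase Pdia4 (0.59), Pdia6 (0.54) and the chaperone Hspa5 (BiP, 0.32) were higher on the array labelled knockout, and Herpud1 (-0.82) and the oxidase Ero1a (-0.80) were lower. The list of ER stress signalling had a median of -0.75, below all random lists: 9 of 23 genes were at least 2-fold lower and 0 at least 2-fold higher. Besides Trib3 and Chac1 these included Aldh1l2 (-1.91), Atf3 (-1.44), Asns (asparagine synthetase, -1.43), Psat1 (serine synthesis, -1.38) and Ddit3 (CHOP, -1.25), and Atf4 itself was at -0.94. The sensor genes Ern1 (-0.37), Atf6 (-0.24) and Eif2ak3 (-0.10) and the factor Xbp1 (-0.08) differed by less than 1.5-fold. The median of this list therefore does not show that ER stress itself was lower. The CREB3 and ATF6 family (8 genes) had a median of -0.10 (percentile 4.06) that depended on the floor, at -0.22 (percentile 0.14) without one and 0.04 (percentile 43.0) with a higher one. Of its members, Creb3l3 was 4.31-fold lower, at 8.74 in wild type and 6.63 on the array labelled knockout.

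The median of the cartilage matrix list was -0.18, below all random lists, with 17 of 23 genes below 0; Frzb was at least 2-fold lower, and Cilp was 2.15-fold higher. Col9a1 (-0.67), Comp (-0.66) and Hapln1 (-0.50) were lower by less than 2-fold, and the major collagen Col2a1 (-0.03) and the proteoglycan Acan (-0.18) differed little. Collagen modification had a median of -0.13 (24 genes, percentile 0.03), or -0.0775 with the floor at the 75th percentile, with the prolyl hydroxylases P4ha2 (-0.99) and P4ha1 (-0.69) lowest. The chondrogenic regulators were at 0.05 (13 genes, percentile 51.1), with Sox9 at -0.19. Hypertrophy and ossification had a median of 0.18 (17 genes, percentile 99.2): Dmp1, a bone matrix phosphoprotein, was 2.74-fold higher and Vegfa, the angiogenic growth factor, 2.92-fold lower.

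Hypoxia-induced and glycolytic genes had a median of -0.69, below all random lists, and 7 of 21 were at least 2-fold lower. Besides Egln3, Car9 and Vegfa these included Pdk1 (-1.41), Bnip3 (-1.39), Ankrd37 (-1.28) and the glucose transporter Slc2a1 (-1.11), and the glycolytic enzymes ranged from Hk2 (-0.98) and Pgk1 (-0.72) to Ldha (-0.11) and Pkm (0.19). The interferon response list had a median of -0.44, below all random lists, with 19 of 20 genes below 0. Usp18 (-1.07) was at least 2-fold lower. Cxcl10 counted as such by its difference (-1.39), but its value on the array labelled knockout lay below the floor, so it was at least 1.89-fold lower. Markers of other cells differed between the same arrays. Endothelial and adipocyte markers were at -0.60 (6 genes, percentile 0.01), or -0.15 (percentile 1.18) without a floor, with the adipocyte gene Fabp4 2.66-fold lower and the endothelial genes Egfl7 (-0.81) and Kdr (-0.71) next. Neural and Schwann markers were at 0.54 (6 genes, above all random lists), with Stmn2 and Tubb3 (2.03-fold) higher, but at 0.11 without a floor, within the range of random lists (percentile 93.8). Skeletal muscle markers were at 0.15 (8 genes, percentile 98.0), a median that was -0.022 without a floor. Fibroblast markers (-0.03, 23 genes, percentile 7.58) lay within the range of random lists, although Mfap5 (2.01-fold) and Cd34 (log2 difference 1.00) were higher. Blood and macrophage markers (-0.04, 19 genes, percentile 4.76) and ribosomal proteins (0.02, 24 genes, percentile 34.7) lay within it too. Some fibroblast and macrophage markers were bright in wild type, such as Col1a2 (14.86 log2 units) and Lyz2 (14.13), whereas Cd34 was at 6.72. Among cartilage matrix genes there, Fmod was at 14.25, Col2a1 at 11.60 and Acan at 8.40. Values of different probe sets do not compare amounts between genes. In the hypertrophy and ossification list, Ibsp (13.65) and Alpl (12.14) were bright in wild type too, whereas Ihh was at 7.04. The differences therefore need not come from chondrocytes alone.

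**Figure D1:**
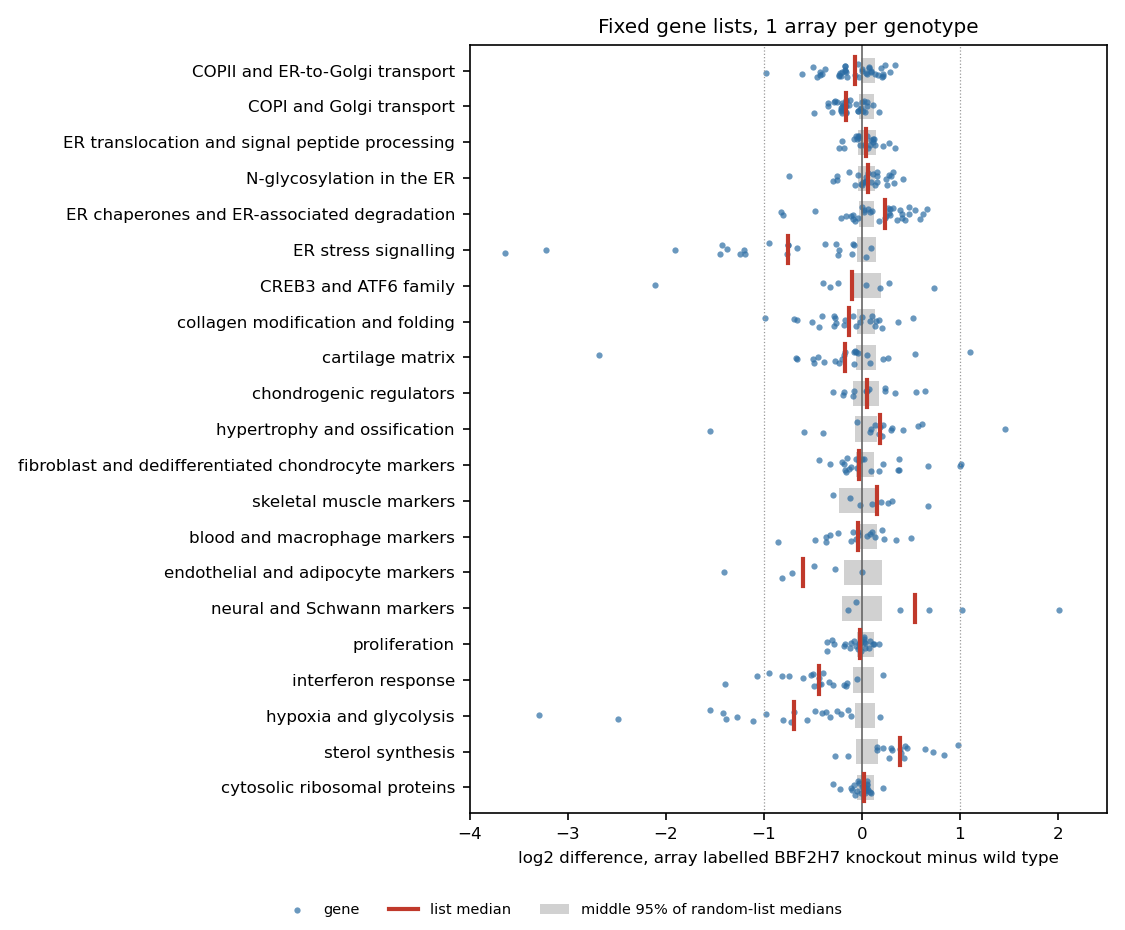
Log2 difference between the array labelled BBF2H7 knockout and the wild-type array for each measured gene (points) of the 21 fixed lists, with the list median (red line) and the middle 95% of the medians of 10000 expression-matched random lists (grey bar). ER stress signalling (median -0.75) and hypoxia and glycolysis (-0.69) lie far to the left, and ER chaperones (0.23) lie to the right.

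The 2-colour array asked which genes the BBF2H7 N-terminal part raises in knockout cells. In the likely direction, 1740 of 14169 genes (12.3%) were at least 2-fold higher in infected cells and 1400 (9.88%) at least 2-fold lower. With the sign turned these numbers change places. The highest ratios were those of cytokines and chemokines: Cxcl2 had a log2 ratio of 11.48, Cxcl5 7.40, Il6 7.26, Ccl2 7.20, Cxcl1 7.10, Csf3 6.10 and Ccl7 6.08. The stromelysin gene Mmp3 (7.15), the growth factor gene Ereg (6.49) and the cyclooxygenase gene Ptgs2 (6.03) were the other members of the 10 highest. Each of these ratios, like the lowest ones below, came from 1 probe. Channel signals were not among the values used, so whether both channels lay above background could not be checked. Size and order of these ratios are therefore uncertain. Cxcl2, Cxcl5, Il6 and Csf3 had no 1-symbol probe set above the 1-colour floor. The lowest were Car3 (-7.58), the hypertrophic chondrocyte channel Panx3 (-6.70), the lipogenic regulator Thrsp (-6.62), the imprinted gene Mest (-6.10), the bone matrix genes Omd (-6.01) and Ibsp (-5.35), the cartilage matrilin Matn3 (-4.60), Lrrc17 (-4.35) and the fat cell genes Cidea (-4.30) and Adipoq (-4.23).

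Sec23a had a log2 ratio of 2.32, the highest of the COPII list; its sign was among the grounds for the direction and is no separate result. That list had a median of 0.47 (37 genes, percentile 99.9), with 7 genes at least 2-fold higher and 1 at least 2-fold lower, Rab1b (-1.24). Mia3, which loads collagen into COPII vesicles, was at 1.63, Mcfd2 at 1.52 and Sec24a at 1.28. ER translocation had a median of 0.62 (23 genes, percentile 99.9), with 6 genes at least 2-fold higher, among them Sec63 (1.43) and the SRP receptor subunit Srprb (1.34). COPI and Golgi transport (0.25, 35 genes, percentile 95.4) and N-glycosylation (0.01, 24 genes, percentile 52.9) lay within the range of random lists. ER chaperones had a median of 1.63, above all random lists, with 24 of 34 genes at least 2-fold higher and 0 lower, among them Derl3 (5.19), Ero1a (5.09), Sdf2l1 (3.92), Creld2 (3.40) and Hspa5 (3.33). ER stress signalling was also at 1.63, above all random lists, with 15 of 23 genes at least 2-fold higher, among them Ddit3 (3.83), Slc7a11 (3.27) and Chac1 (2.91). In the CREB3 and ATF6 family (8 genes, median -0.02, percentile 47.3) Atf6 was at 1.25. Collagen modification was at -0.17 (25 genes, percentile 16.6), with 5 genes at least 2-fold higher, P4ha2 the highest, and 5 at least 2-fold lower, Loxl1 (-2.04) the lowest.

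In the likely direction, most cartilage matrix genes were lower in the infected cells. In that list 20 of 27 genes were at least 2-fold lower and 1 at least 2-fold higher, Itih5 (1.42), with a median of -1.95, below all random lists. Besides Matn3 these included Cnmd (-4.19), Col2a1 (-3.86), Prelp (-3.60) and Hapln1 (-3.32), whereas Acan was at 0.62. The chondrogenic regulators had a median of -0.69 (16 genes, percentile 0.09), with 5 genes at least 2-fold lower and 5 above 0, Cytl1 at -3.15 and Sox9 at -0.97, and hypertrophy and ossification one of -0.88 (20 genes), or -1.62 over the 15 genes that could be matched on 1-colour expression, below all random lists in both. In the hypertrophy list 10 genes were at least 2-fold lower, among them Panx3, Ibsp and the receptor Pth1r (-3.77), and 6 at least 2-fold higher, among them Mmp9 (4.93), Vegfa (4.25) and Mmp13 (4.15).

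All 22 measured genes of the interferon response lay above 0, with a median of 2.56 and 19 at least 2-fold higher, among them Cxcl10 (5.69), Ccl5 (5.46) and Ifit3 (4.54). Hypoxia and glycolysis had a median of 1.46, with 12 of 22 genes at least 2-fold higher, such as Adm (5.24) and Vegfa. Both medians were above all random lists. The sign of the interferon genes, too, was among the grounds for the direction. Endothelial and adipocyte markers had a median of -0.95 (15 genes, below all random lists) but went opposite ways: all adipocyte genes were below 0, with Adipoq, Cfd (-3.33) and Fabp4 (-2.56) lowest, and most endothelial genes were above 0, with Pecam1 (0.70), Cdh5 (0.52) and Kdr (0.49) highest. The median was -0.72 for skeletal muscle (20 genes, percentile 0.03), -0.69 for fibroblast markers (23 genes, percentile 0.02) and -0.42 for blood and macrophage markers (18 genes, percentile 1.87, or 9.28 when random lists were matched on 1-colour expression). Neural and Schwann markers were at 0.03 (11 genes, percentile 55.5), or -0.46 over 6 genes with matched random lists (percentile 8.50), and ribosomal proteins at -0.25 (27 genes, percentile 6.25). Dye and virus cannot be separated from the N-terminal part on this array, which had no dye swap and no named control virus.

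**Figure D2:**
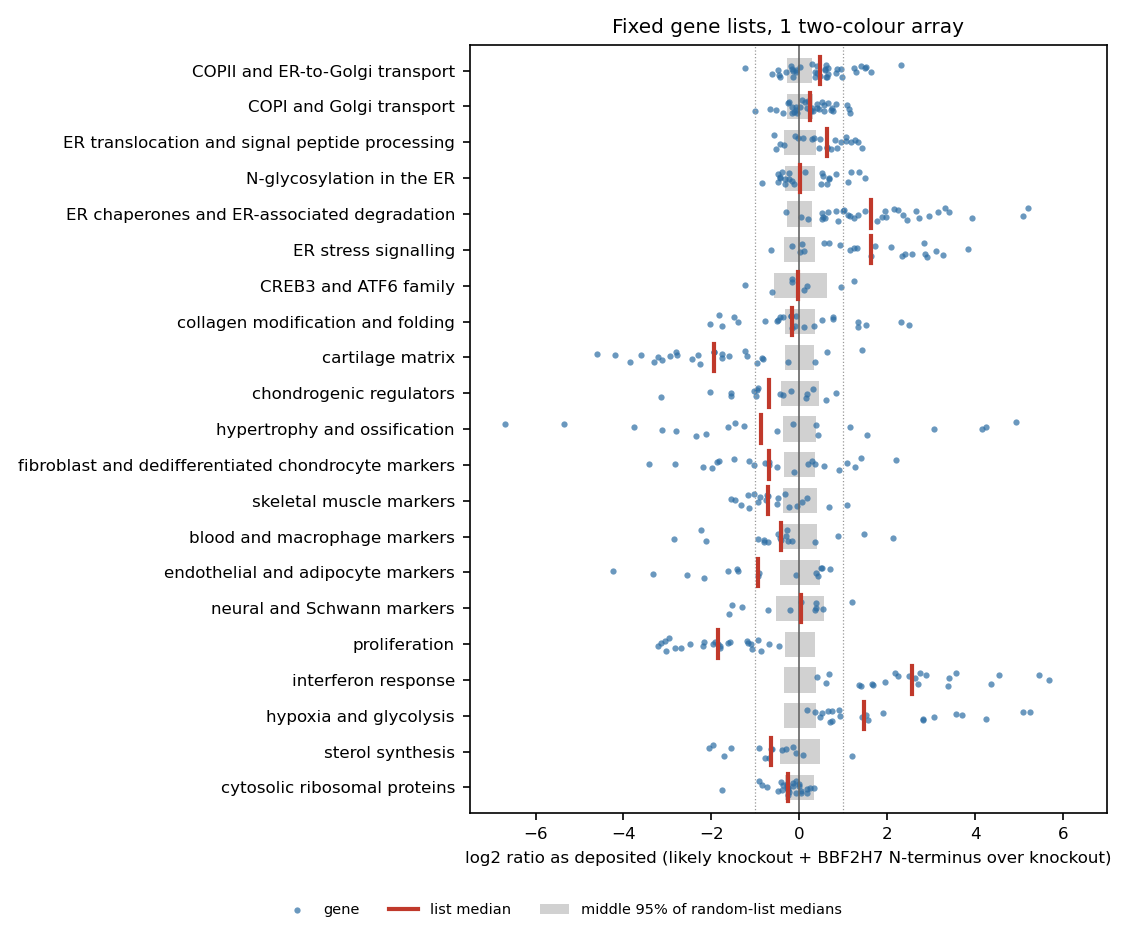
Log2 ratio on the 2-colour array, in its likely direction of infected over knockout, for each measured gene (points) of the 21 fixed lists, with the list median (red line) and the middle 95% of the medians of 10000 random lists (grey bar). Interferon response (2.56), ER chaperones (1.63) and ER stress signalling (1.63) lie to the right, and cartilage matrix (-1.95) to the left.

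The design text describes a search for BBF2H7 targets through genes raised by the N-terminal part. Of 9950 genes measured on both platforms, 72 were at least 2-fold lower on the array labelled knockout, and 46 of these (63.9%) were at least 1.5-fold up on the 2-colour array, where 22.6% of all genes were. Independent lists would share 16.3 genes. A further 10 of the 72 were at least 1.5-fold down, against 16.3 for independent lists, and this is the overlap that would count with the sign turned. They included Frzb (-2.68 and -2.27), Rbp4 (-2.61 and -0.96) and Fabp4 (-1.41 and -2.56). Of the 41 genes at least 2-fold higher on the array labelled knockout, 18 were at least 1.5-fold down and 8 up, against 9.27 each for independent lists. Across the 9950 genes Spearman's rho was -0.25 and Pearson's r -0.25, with a covariance of -0.071 (genes are not independent replicates). Cells labelled knockout enter both comparisons, and with 1 array each the part of these values that comes from them could not be separated. In the likely direction, a value particular to shared knockout cells would give opposite signs in the 2 comparisons. That is the direction of the excess of 46 over 16.3 and of the negative rho, so independence may be too low a standard.

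Of the 46 genes lower on the array labelled knockout and up in the likely direction, 31 were in none of the lists. The ER stress signalling list held 7, the hypoxia and glycolysis list 6 and the interferon response list 2. With the sign turned, each of these lists would hold 0 such genes. The medians of these lists were themselves low in the first comparison and high in the second, and within each list independence of both limits would give 5.82, 4.80 and 1.89 genes. Among the 46 genes were Mmp3 (-1.20 on the 1-colour arrays and 7.15 on the 2-colour array), Ptgs2 (-1.33 and 6.03), Cxcl10 (-1.39 and 5.69), Egln3 (-3.29 and 3.56), Trib3 (-3.64 and 2.86) and Car9 (-2.49 and 3.71). Others were Chac1, Gal, Vegfa, the metallothionein Mt2, the peptide hormone Adm2, Ddit3, Cth, Aldh1l2, the glycine transporter Slc6a9, Atf3, the cytokine receptor Il7r, Slc2a1, Bcat1 and Hsd17b1. Mmp3, Cxcl10, Egln3, Gal, Adm2, Cth, Il7r and Hsd17b1 lay below the floor on the array labelled knockout, so their differences there are uncertain in size. The named genes were picked and are listed by the sum of both sizes, so their choice and order are uncertain too. Raised to the floor, Cxcl10 no longer met the first limit. None of the 36 COPII genes and none of the 34 chaperone genes measured on both platforms met both limits. Sec23a, with a difference of -0.50 on the 1-colour arrays and a log2 ratio of 2.32, fell short of the first limit.

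**Figure D3:**
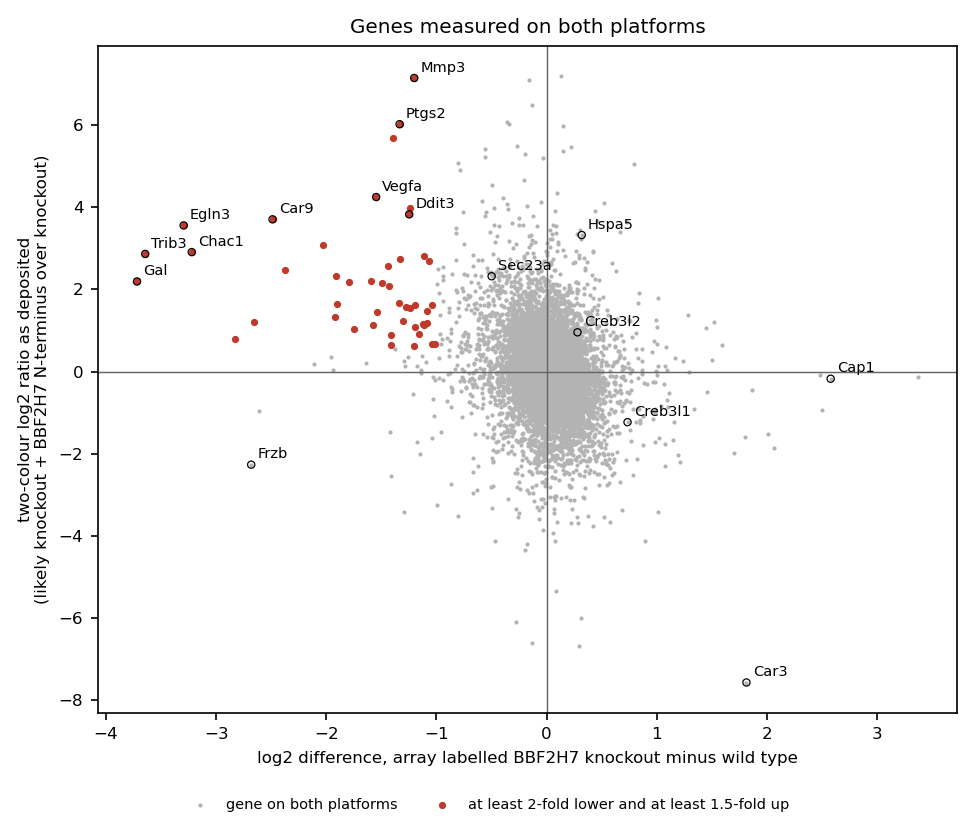
Log2 difference between the array labelled BBF2H7 knockout and wild type (x) against the 2-colour log2 ratio in its likely direction (y) for 9950 genes, with the 46 genes at least 2-fold lower and at least 1.5-fold up in red and selected genes named. Trib3, Egln3 and Chac1 lie at the upper left, Car3 at the lower right, and Sec23a and Hspa5 lie above 0 on the y axis on opposite sides of 0 on the x axis.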

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

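The settings with matched 2-colour lists and with values raised to the floor were added after the values were seen. Counts depended on the limits by construction. The 81 genes lower and 46 higher on the array labelled knockout became 271 and 206 at 1.5-fold, 23 and 12 at 3-fold, and 35 and 19 with the floor at the 75th percentile, which tested fewer genes. On the 2-colour array 3215 genes were higher and 2935 lower at 1.5-fold. The overlap of 46 genes became 135 at 1.5-fold in both. With values below the floor raised to it, the counts were 77, 43 and 45. Other planned settings left these counts within 1.5 times, and the log2 difference of Creb3l2 stayed between 0.16 and 0.28. Of the lists outside the middle 95% of random lists on the 1-colour arrays, 11 of 13 stayed there on the same side in every setting. The exceptions were skeletal muscle, whose median turned from 0.15 to -0.022 (percentile 55.9) without a floor and which lay at percentile 93.4 of unmatched random lists, and neural and Schwann markers (0.11, percentile 93.8, without a floor). Endothelial and adipocyte markers ranged from -0.60 to -0.15. With the median over probe sets ER stress signalling was at -0.69 and ER chaperones at 0.13 (percentile 97.54). ER chaperones were at 0.18 both without _x_at and _s_at probe sets and after the lowess curve, which put COPII at -0.12, COPI at -0.21 and ER translocation at -0.0126 (percentile 32.8), so the last changed sign within the range of random lists. The cause was not tested. With the sign of the 2-colour ratio turned, the medians were -0.47 for COPII, -0.25 for COPI, -0.62 for ER translocation, -1.63 for both ER chaperones and ER stress signalling, -2.56 for interferon, -1.46 for hypoxia, 1.95 for cartilage matrix, 0.69 for chondrogenic regulators, 0.88 for hypertrophy, 0.69 for fibroblast, 0.72 for muscle, 0.42 for blood, 0.95 for endothelial and adipocyte markers, 1.86 for proliferation and 0.65 for sterol synthesis. The turned sign, which turns every 2-colour value, and the raised floor values are left out of the next count. Of 362 values of named genes under the other alternatives, 349 stayed within the spread between probes and 0 changed sign. Many of these values could not move. Each named gene with a ratio had 1 probe on the 2-colour array, and median centring shifted its ratio by only 0.00065. Genes with 1 probe set above the floor were likewise fixed under the median over probe sets. Leaving out an array leaves no comparison. No paired analysis was possible because each group has 1 array.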

Other observations

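The medians of the sterol synthesis list lay on opposite sides of 0 in the 2 comparisons. On the array labelled knockout the list had a median of 0.39 (17 genes, above all random lists), with Dhcr7 (0.98), Mvd (0.84) and Idi1 (0.72) highest and 2 genes below 0. On the 2-colour array, in its likely direction, the median was -0.65 (15 genes, percentile 0.19), with Mvk (-2.06), Nsdhl (-1.97) and Dhcr7 (-1.71) lowest and Pmvk (1.19) highest. Insig1, Sc5d, Srebf2 and Pmvk had the same sign in both. Proliferation genes did not follow this pattern. They were at -0.02 between the 1-colour arrays (26 genes, percentile 10.1), where Mki67 differed by 0.11, whereas all 25 measured on the 2-colour array were below 0, with a median of -1.86 and 21 at least 2-fold lower, among them Cdc20 (-3.21), Plk1 (-3.15) and Ccnb2 (-3.06).

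The tests of swapped labels, of the unfolded protein response as a whole, of oxygen or medium, of the infection and of OASIS were chosen after values they use, or single genes of their lists, had been seen; those of the neighbours of Creb3l2 and of immune genes that depend on BBF2H7 were set down before.

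Creb3l2 was not lower on the array labelled knockout. Swapped labels of the 1-colour arrays stay open. The COPII list lay at percentile 0.08, and the rule first written would have counted that against a swap, given that BBF2H7 raises these genes as on the 2-colour array (percentile 99.9). The rule was changed after the value was seen, because the direction of that array was itself read partly from Sec23a, a COPII gene, so the order of the labels cannot be told apart by this list. The 200 measured genes around Creb3l2 differed by a mean of 0.20 log2 units, at percentile 69.4 of all runs of 200 neighbouring genes, and equal genotypes at the locus cannot be told apart from different ones by this value. OASIS knockout cells stay open too, because the position of the Creb3l1 probe set (difference 0.73) relative to a deletion is not known. Xist was at 7.85 log2 units in wild type and 5.26 on the array labelled knockout. Another of its probe sets, with a mean below the floor, was at 7.05 and 3.72. In wild type Xist and the Y-linked Eif2s3y (8.66) both lay above the floor, as in RNA from embryos of both sexes. The sex make-up of the 2 cultures may therefore differ. It is not given in the sources used here and was not tested.

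The median of the ER stress signalling list was lower on the array labelled knockout, with Trib3, Chac1, Aldh1l2 and Atf3 lowest. Its sensor genes Ern1 (-0.37), Atf6 (-0.24) and Eif2ak3 (-0.10) and the factor Xbp1 (-0.08) differed by less than 1.5-fold. A weaker unfolded protein response as a whole would lower ER chaperones too, but their median lay at percentile 100 of random lists. This argues against it for these 2 arrays only. With the median over probe sets the chaperones were at 0.13 (percentile 97.54). Of the 35 chaperone genes 10 lay below 0, among them Herpud1 (-0.82) and Ero1a (-0.80). A difference in oxygen or medium between the 2 cultures is a candidate explanation that the values allow: the hypoxia and glycolysis list had a median of -0.69, below all random lists. An effect of the genotype stays open as well, since each genotype is 1 culture.

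Immune genes had the largest 2-colour ratios. Interferon response genes that depend on BBF2H7 would be lower on the array labelled knockout, and that list was, with a median of -0.44, which the state of that culture may equally explain. The cytokines and chemokines with the largest ratios are not members of the interferon response list, so its medians do not test them. Of these cytokines and chemokines, Cxcl2, Cxcl5, Il6 and Csf3 had no 1-symbol probe set above the floor on the 1-colour arrays. Differences below the floor were not compared for these genes. The other 3 are too few to decide. Ccl2 differed by 0.14, Cxcl1 by -0.16 and -0.58 on its 2 probe sets, and Ccl7 by -0.36. The value of Ccl7 on the array labelled knockout lay below the floor. A response to the infection itself stays open. The 13 interferon genes that differed by less than 1.5-fold between the 1-colour arrays had a median log2 ratio of 2.49 (the middle 95% of random lists reached 0.52), but the direction was read partly from interferon genes, and without a control virus infection and N-terminal part cannot be told apart.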
